A study of Vigna unguiculata with 30 samples.

How the data were processed

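Leaf RNA was measured by sequencing in 30 cowpea libraries, 5 from each of 6 groups defined by canopy position (bottom, middle, top) and developmental stage (R1, R3). Per the labels' protocols, plants grew in the ground of a greenhouse under supplemental light, RNA was purified with a MagMAX kit, and libraries were made from polyA RNA with a Kapa HyperPrep mRNA kit. The authors deposited a table of raw counts per gene and a table of normalized counts; HISAT2, featureCounts and DESeq2 are named, without versions or roles, per the submitters' processing notes. The genome build and the strand setting of the counting are not given in the sources used here. Gene identifiers carry the annotation version 1.2, and the count table gives each gene's chromosome, exons, strand and length. The normalized table, a signal that is never negative per its deposited values, was tested against the raw counts: 100% of its values gave the raw count after multiplying by 1 factor per library (tolerance 0.001), and the factors equalled the DESeq2 size factors of the raw counts. All tests therefore used the deposited raw counts. Every value column was matched to 1 sample by its label, and 0 were left over.

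Groups and replicate numbers came from the sample titles. The 60 pairs of libraries within groups differed by 16.6 to 188 times the sampling noise (chi-square per degree of freedom over genes with at least 20 counts in the pair), so no library was counted as a copy of another. Genes were kept by the default rule of filterByExpr by group, which left 20284. Counts were scaled by TMM and fitted with the quasi-likelihood method of edgeR 4.0.16 (trended dispersion, all 6 groups in 1 fit, 24 residual degrees of freedom) in R 4.3.3. The 9 comparisons of 2 groups (3 pairs of positions at each stage, and R3 versus R1 at each position) and the interaction of stage with top versus bottom were contrasts of that fit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05; counts at 2-fold or more are given beside. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. The comparisons, tests and alternatives were fixed before the data were examined, except where a choice is said to have been made after. Scores of gene groups are means of log2 CPM (edgeR, prior count 2) after centring each gene over the 30 libraries. They were tested only in libraries outside the contrast that chose the genes. The filter, scaling and dispersion behind each call came from the fit of all 6 groups, so they also used the libraries scored. The tests were two-sided exact permutation tests over all 252 assignments of 10 libraries, whose smallest p is 0.0079. Principal components used log2(CPM + 1).

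Named genes followed a rule fixed beforehand: where identifiers cannot be tied to names, at most 2 up and 2 down per comparison, those with the largest fold changes among called genes with a mean of at least 5 CPM and non-overlapping CPM ranges in the 2 groups, and, by the same number, the 2 with the highest mean CPM for each position class and for the even genes (the rule gave 3 per class for genes with names and no separate number without). Of the gene models, 0 matched a gene in the RefSeq table used (assembly ASM411807v2), and the files do not pair identifiers with names. The 41 gene lists drawn up beforehand, markers of cell types included, rest on product names and were therefore not analysed here, and no set test was run on them. Exons of 1084 gene models overlap those of another, 919 of them on the opposite strand; 797 tested genes have such an overlap and none of the named genes does. Counts of overlapping genes, and of near-identical copies, are uncertain because the handling of shared reads is not given in the sources used here.

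On counts simulated for the real genes, with 200 genes changed in top R1 libraries, edgeR recovered 22%, 58%, 80% and 90% of the genes changed 1.5, 2, 4 and 8-fold in top versus bottom at R1, among 20284 genes, and 4.58% of its calls were false; DESeq2 recovered 34%, 62%, 88% and 92%, with 15.3% false. The simulated counts were drawn independently for each gene, without deviations shared between genes or by replicate number. They held far fewer changed genes than were called in the real libraries. The recovered and false shares may therefore not hold for the real data. The depth of 10.5 to 17.4 M counts sets a floor: 3 counts over the 5 bottom R1 libraries correspond to 0.0409 CPM. Fold bounds use that floor over the group, and ratios with 1 to 3 counts carry an exact Poisson interval at 95%, for counting error only.

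Alternatives were size factors of DESeq2 within edgeR, no filter beyond 1 count, the replicate number as a block, DESeq2 1.42.0, a fit of only the groups compared, a 2-fold threshold, and leaving out each library in turn. Added after seeing the data were scaling by library size alone, thinning all libraries to the smallest total, a block of replicate number within stage, and leaving out every pair of libraries of a group in turn, 60 pairs in all. That last set replaced a fit without 1 pair of top R3 libraries, which had been chosen because of their values. That pair is 1 of the 60, and where it gives the end of a printed range the text says so. Whether equal replicate numbers pair the samples was checked on deviations from the group means: between bottom R1 and middle R1 all 5 same-numbered pairs correlated, from 0.19 to 0.52, so the numbers pair those samples by this criterion, which comes from the data and not from the labels. None of the other 14 pairs of groups met it, but sharing by number is not shown to be confined to these 2 groups: all 5 correlations were positive between bottom R3 and middle R3 (0.05 to 0.46) and between top R1 and top R3 (0.01 to 0.53). Exact tests with labels exchanged only within same-numbered pairs, whose smallest two-sided p is 0.0625, were therefore added after seeing the data. Figures were drawn with matplotlib.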

Results

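The series recorded the leaf transcriptome of cowpea (Vigna unguiculata), a grain legume, in the line IT97K-499-35 grown in a greenhouse. Leaf punches were taken at the bottom, middle and top of the canopy at 2 developmental stages, R1 (week 5.5 from planting) and R3 (week 6.5). Each of the 6 combinations of position and stage had 5 libraries made from polyA RNA, 30 in all. The labels call the replicates biological without saying whether each came from its own plant. The p-values therefore set differences against the variation between these samples, which may not be that between plants. In edgeR this variation is estimated over all 6 groups. The series title names native promoters, for which the position and stage at which a gene is expressed is the question asked here. Libraries held 10.5 to 17.4 M counts (M, mega; median 12.7 M) over 31948 gene models. Of these, 27613 had a count in some library and 20284 passed the filter on low counts. Between 22033 and 23951 gene models had at least 1 count in a library. Levels are CPM (counts per M counts) on library sizes scaled by the trimmed mean of M values (TMM), given as mean ± SD over 5 libraries. The gene identifiers come without product names, so gene models are given by identifier and by the coordinates of the deposited count table, whose genome build is not given in the sources used here.

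Canopy position was the main axis along which the libraries differed. The first principal component of log2(CPM + 1) held 43.1% of the variance, and on it all 10 top libraries scored 25.9 or more and all 10 bottom libraries scored -19.2 or less. At R1, middle libraries (-15.6 to 35.7) lay above the bottom ones (highest -19.2) and overlapped the top ones (lowest 34.8). At R3 they (-53.4 to 20.4) lay between bottom (highest -56.7) and top libraries (lowest 25.9). The second component held 13.6%. The gene model Vigun01g219300 (chromosome 1, 39315283 to 39320127, minus strand, 19 exons), singled out after its values were seen, was the most abundant in 28 of the 30 libraries. Its level was 13200 ± 4370 CPM in bottom, 25100 ± 8090 CPM in middle and 19500 ± 5450 CPM in top leaves at R1. At R3 it was 17200 ± 5440 CPM in bottom, 30500 ± 8930 CPM in middle and 30400 ± 6000 CPM in top leaves. Its edgeR test passed for top versus bottom at R3 (log2 fold change 0.82, SE 0.31, adjusted p = 0.031) and missed the threshold for middle versus bottom at R1 (adjusted p = 0.064) and at R3 (0.059). These calls lie at the threshold. The call at R3 ended without bottom replicates 2, 4 and 5 (adjusted p = 0.072, 0.081 and 0.063), top replicates 3 and 5 (0.064 and 0.075), TMM scaling (0.058) or the filter (0.092), and in a fit of the 2 groups alone (0.059). Middle versus bottom passed with DESeq2 (0.012 at R1, 0.015 at R3), at R1 without TMM scaling (0.041) or bottom replicate 4 (0.047), and at R3 without bottom replicate 1 (0.045) or middle replicate 4 (0.03). The 10 most abundant genes of a library together took 9.82% ± 0.81 of its counts in top and 5.96% ± 1.12 in bottom leaves at R3 (exact permutation test, two-sided, p = 0.00794, adjusted over 9 comparisons 0.0357). At R1 they took 8.76% ± 1.19 in middle and 6.25% ± 0.942 in bottom leaves, with the same exact p and adjusted value. Top versus bottom at R1 (adjusted 0.0571) and middle versus bottom at R3 (0.0536) missed the threshold, and top leaves differed between the stages (exact permutation p = 0.0159, adjusted 0.0477). With labels exchanged only within same-numbered pairs the exact p was 0.0625 for middle versus bottom at R1 and 0.125 for the stages in top leaves. The smallest p of that exchange is 0.0625, so it could pass for neither and does not decide them.

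**Figure D1:**
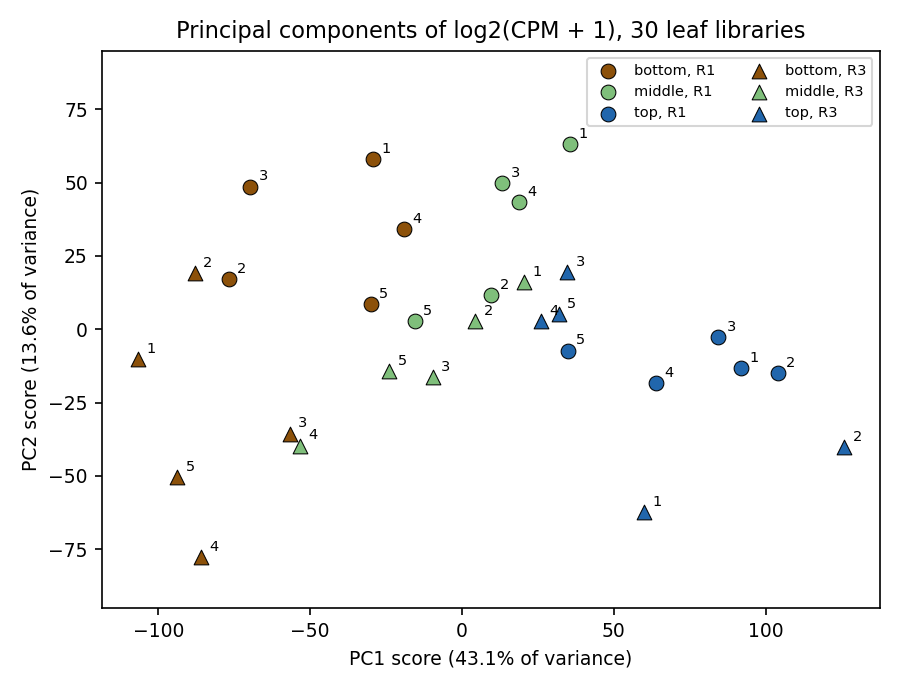
Scores of the 30 libraries on the first (43.1% of variance) and second (13.6%) principal components of log2(CPM + 1); colour is canopy position, shape is stage and numbers are replicates. All top libraries lie at 25.9 or more on the horizontal axis and all bottom libraries at -19.2 or less.

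The first question was which genes differed between the top and the bottom of the canopy at R1. Vigun03g140800 (chromosome 3, 14048370 to 14050400, plus strand, 1 exon) stood at 149 ± 119 CPM in top leaves and at 0 in every bottom library. Against a floor of 3 counts over the 5 bottom libraries, it was at least 3541-fold higher at the top. Vigun09g263100 (chromosome 9, 42756810 to 42758313, plus strand, 4 exons) stood at 42.2 ± 22.8 CPM in top leaves, at least 1028-fold higher than bottom leaves, which again had 0 counts. In the other direction, Vigun08g220100 (chromosome 8, 37901364 to 37906826, minus strand, 18 exons) fell from 207 ± 197 CPM in bottom to 1.68 ± 1.28 CPM in top leaves, a log2 fold change of -6.95 (SE 0.98, edgeR adjusted p = 1.4e-05). Vigun08g190300 (chromosome 8, 35807849 to 35809053, plus strand, 3 exons) fell from 55.9 ± 75 to 0.124 ± 0.196 CPM, with bottom libraries from 0.539 to 156 CPM (log2 fold change -8.78, SE 1.72, adjusted p = 0.0003). Without bottom replicate 2 this fold change was -7.92, and without top replicate 5 it was -10.12. Over all genes tested, 8731 (43% of 20284) differed, 4506 higher and 4225 lower at the top. Of these, 4601 differed at least 2-fold, 2882 of them higher and 1719 lower. Without TMM scaling the split was 3622 higher and 5448 lower, and the median of all genes moved by -0.15 (log2). Floors and intervals on low counts cover counting error only.

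At R3, 10534 genes differed between top and bottom leaves (51.9%), 5300 higher and 5234 lower at the top, and 5980 of them at least 2-fold, 3579 higher and 2401 lower. Vigun10g098300 (chromosome 10, 28797052 to 28798045, minus strand, 2 exons) was at 176 ± 271 CPM in top and 0.059 ± 0.0625 CPM in bottom leaves (log2 fold change 11.28, SE 1.65, edgeR adjusted p = 6.2e-06). Vigun06g219300 (chromosome 6, 32985796 to 32986131, plus strand, 1 exon) was at 433 ± 517 and 0.267 ± 0.15 CPM (log2 fold change 10.64, SE 1.63, adjusted p = 1.1e-05). Both SDs at the top exceed the mean, and the top libraries of Vigun10g098300 ranged from 6.07 to 629 CPM. Without top replicate 2 their log2 fold changes were 9.80 and 9.74. Vigun03g315200 (chromosome 3, 50914555 to 50917245, minus strand, 4 exons) was at 101 ± 111 CPM in bottom leaves and had 2 counts in the 5 top libraries together, a ratio of 3135 with a 95% counting interval of 868 to 25891 (edgeR adjusted p = 0.0002). The ratio of Vigun03g315200 was 1451 without bottom replicate 2 and 5176 without top replicate 3. Vigun08g190300 was lower at the top here too, at 0.0958 ± 0.105 against 92.1 ± 85.8 CPM (log2 fold change -9.71, SE 1.77, adjusted p = 8.3e-05), with -9.11 without bottom replicate 2 and -10.33 without top replicate 4. TMM scaling takes most genes as unchanged, whereas 51.9% were called here. Its mean factor at R3 was 0.886 in top and 1.096 in bottom libraries (exact permutation test, two-sided, p = 0.00794, adjusted over 9 comparisons 0.0357). The balance of higher and lower genes therefore depends on the scaling and is uncertain. Without TMM scaling the split was 3847 higher and 8054 lower, with the median of all genes moved by -0.31 (log2). Of the 10534 genes, 9081 were then called in the same direction and 58 changed the sign of their fold change. With 2 libraries of either group left out, over all 20 such pairs (a choice made after seeing the data), 8425 to 10530 genes differed; at R1 the range was 5524 to 9064, the lowest without bottom replicates 2 and 3.

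**Figure D2:**
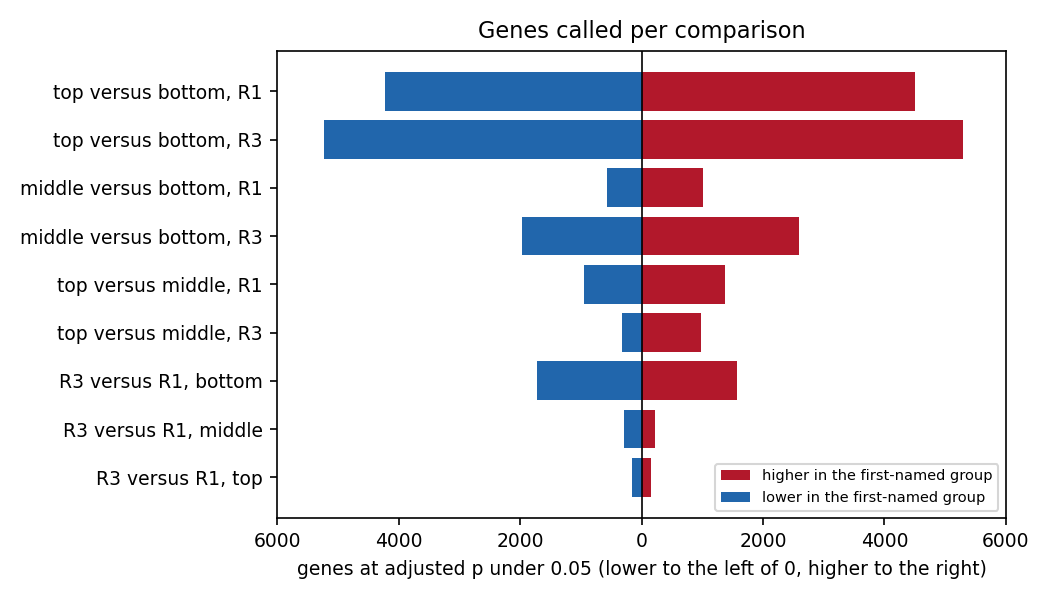
Number of genes at adjusted p under 0.05 in each of the 9 comparisons of 2 groups, with genes higher in the first-named group to the right of 0 and genes lower to the left. Top versus bottom has the longest bars, 8731 genes at R1 and 10534 at R3.

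The top to bottom differences of the 2 stages, which share no library but come from 1 fit with a common filter, scaling and dispersion, went together. Across the 20284 genes, which are not independent replicates, the log2 fold changes at R1 and R3 had Pearson's r = 0.80 and Spearman's rho = 0.78. There were 3597 genes higher at the top in both stages, where independent lists of these sizes would share 1177, and 3130 lower in both, where they would share 1090. The common dispersion can raise these and the later overlaps of lists, and how much was not tested. Only 25 genes were called in opposite directions. The median log2 fold change of the 4506 genes higher at R1 was 1.35 at R1 and 1.45 at R3, and that of the 4225 lower genes was -0.82 and -0.68.

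**Figure D3:**
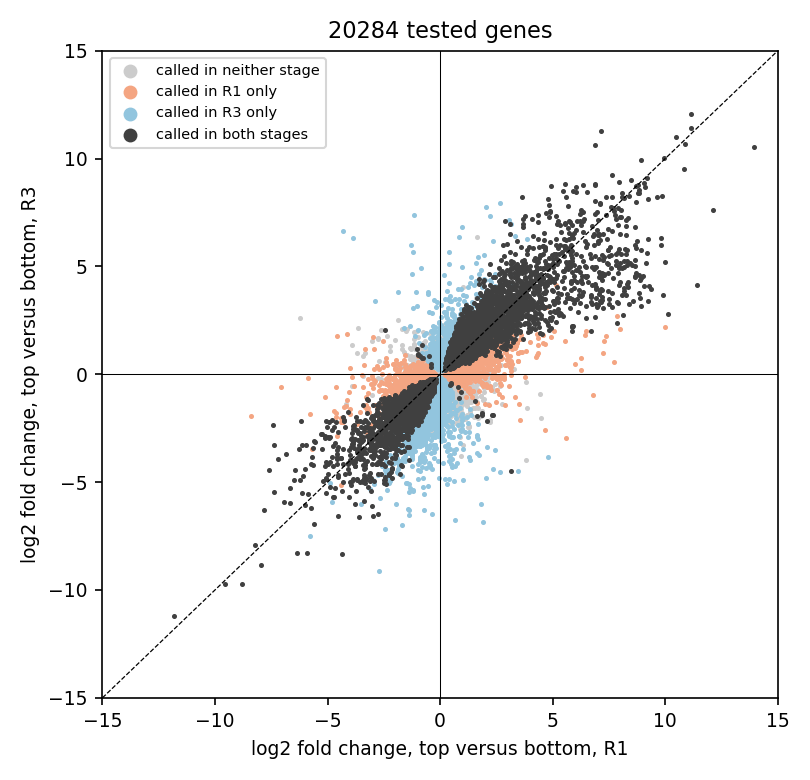
Log2 fold change of top versus bottom leaves at R1 (horizontal) and R3 (vertical) for each of the 20284 tested genes, coloured by the stages in which the gene was called; the dashed line marks equal values. The points follow the diagonal (r = 0.80 across genes), with 25 genes called in opposite directions.

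Middle leaves lay between bottom and top leaves in the genes that separate those. The 4506 genes higher at the top at R1 were scored in R3 libraries as their mean log2 CPM relative to all libraries. The score was -0.84 ± 0.22 in bottom, -0.11 ± 0.25 in middle and 0.65 ± 0.5 in top leaves (SD, n = 5). Middle and bottom leaves did not overlap, nor did top and middle leaves (exact permutation test, two-sided, p = 0.0079 each, the smallest that 5 against 5 can give; adjusted over 24 scores 0.011). The 4225 genes lower at the top at R1 scored 0.57 ± 0.24, 0.02 ± 0.12 and -0.45 ± 0.31 in R3 bottom, middle and top leaves, with the same exact p for both steps. The 5300 genes higher at the top at R3, scored in R1 libraries, gave -0.55 ± 0.25, 0.11 ± 0.16 and 0.82 ± 0.23, again without overlap. The 5234 genes lower at the top at R3 scored 0.30 ± 0.23, -0.14 ± 0.24 and -0.51 ± 0.19 there, with weaker steps from bottom to middle (exact permutation p = 0.024, adjusted 0.026) and from middle to top (exact p = 0.04, adjusted 0.042). These tests ignore replicate numbers, which pair bottom and middle libraries at R1. With labels exchanged only within same-numbered pairs, every step to or from the middle had an exact p = 0.0625. This is the smallest that 5 pairs can give, so no step can pass in that way and the exchange does not decide them.

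Gene by gene, 1581 genes differed between middle and bottom leaves at R1, 1015 higher and 566 lower in the middle, and 4570 at R3, 2593 higher and 1977 lower. Of the higher genes 797 were shared by both stages, where independent lists would share 130, and of the lower genes 418, where they would share 55. The abundant Vigun11g181300 (chromosome 11, 38485436 to 38488718, plus strand, 6 exons) rose from 2250 ± 1070 CPM in bottom to 5410 ± 1280 CPM in middle leaves at R1 (log2 fold change 1.26, SE 0.34, edgeR adjusted p = 0.026) and from 2080 ± 967 to 6960 ± 2000 CPM at R3 (1.74, SE 0.35, adjusted p = 8e-04). Its call at R1 ended without bottom replicates 2 and 3 (adjusted p = 0.08 and 0.09) or middle replicates 1, 2 and 3 (0.056, 0.068 and 0.051), in a fit of the 2 groups alone (0.078) and with a replicate block within stage (0.059). The R1 count was 470 without bottom replicate 2, 460 without bottom replicate 3 and 2485 without bottom replicate 4, and 819, 635, 958 and 924 without middle replicates 1, 2, 3 and 4. DESeq2 called 2552 genes and a fit of these 2 groups alone 808. Over the 20 pairs of libraries left out, the counts ran from 15 to 3148 at R1 and from 1715 to 4883 at R3. Without TMM scaling the splits were 789 higher and 1861 lower at R1 and 1866 and 3491 at R3, with the median of all genes moved by -0.19 and -0.18 (log2).

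Between top and middle leaves 2323 genes differed at R1, 1379 higher and 944 lower at the top. At R3 there were 1288, 971 higher and 317 lower. Vigun01g115300 (chromosome 1, 29196393 to 29203487, plus strand, 5 exons) was higher at the top at R1, 1990 ± 854 against 766 ± 306 CPM (log2 fold change 1.37, SE 0.36, edgeR adjusted p = 0.018), and at R3, 1790 ± 1140 against 682 ± 311 CPM (1.39, SE 0.36, adjusted p = 0.026). Vigun03g020100 (chromosome 3, 1465191 to 1470074, minus strand, 9 exons) was lower at the top, 158 ± 81.4 against 417 ± 67.3 CPM at R1 (-1.40, SE 0.36, adjusted p = 0.016) and 163 ± 85.3 against 395 ± 53.9 CPM at R3 (-1.28, SE 0.35, adjusted p = 0.033). The call of Vigun01g115300 ended at R1 without top replicate 2 (adjusted p = 0.066), and at R3 without middle replicates 3, 4 and 5 (0.059, 0.085 and 0.067) or top replicates 1 and 2 (0.054 and 0.15) and in a fit of the 2 groups alone (0.17). That of Vigun03g020100 ended at R3 without middle replicates 2, 4 and 5 (0.056, 0.082 and 0.074) or top replicates 1 and 2 (0.069 each) and in a fit of the 2 groups alone (0.2). Genes higher at the top at R1 were higher at R3 in 621 cases, where independent lists would share 66. The R1 count was 1213 and 1149 without top replicates 1 and 2 and 1198, 1487 and 1328 without middle replicates 3, 4 and 5, and 3710 in a fit of these 2 groups alone. It was 45 to 2388 over the 20 pairs of libraries left out. The split without TMM scaling was 1495 higher and 649 lower. The R3 count rests on single libraries: it was 529, 83 and 1957 without top replicates 1, 2 and 5, and 2000, 794, 681, 98 and 276 without middle replicates 1, 2, 3, 4 and 5. It was 1 to 2917 over the 20 pairs of libraries left out, 2391 with DESeq2 and 33 in a fit of the 2 groups alone. The split without TMM scaling was 827 higher and 718 lower (median of all genes moved by -0.12).

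**Figure D4:**
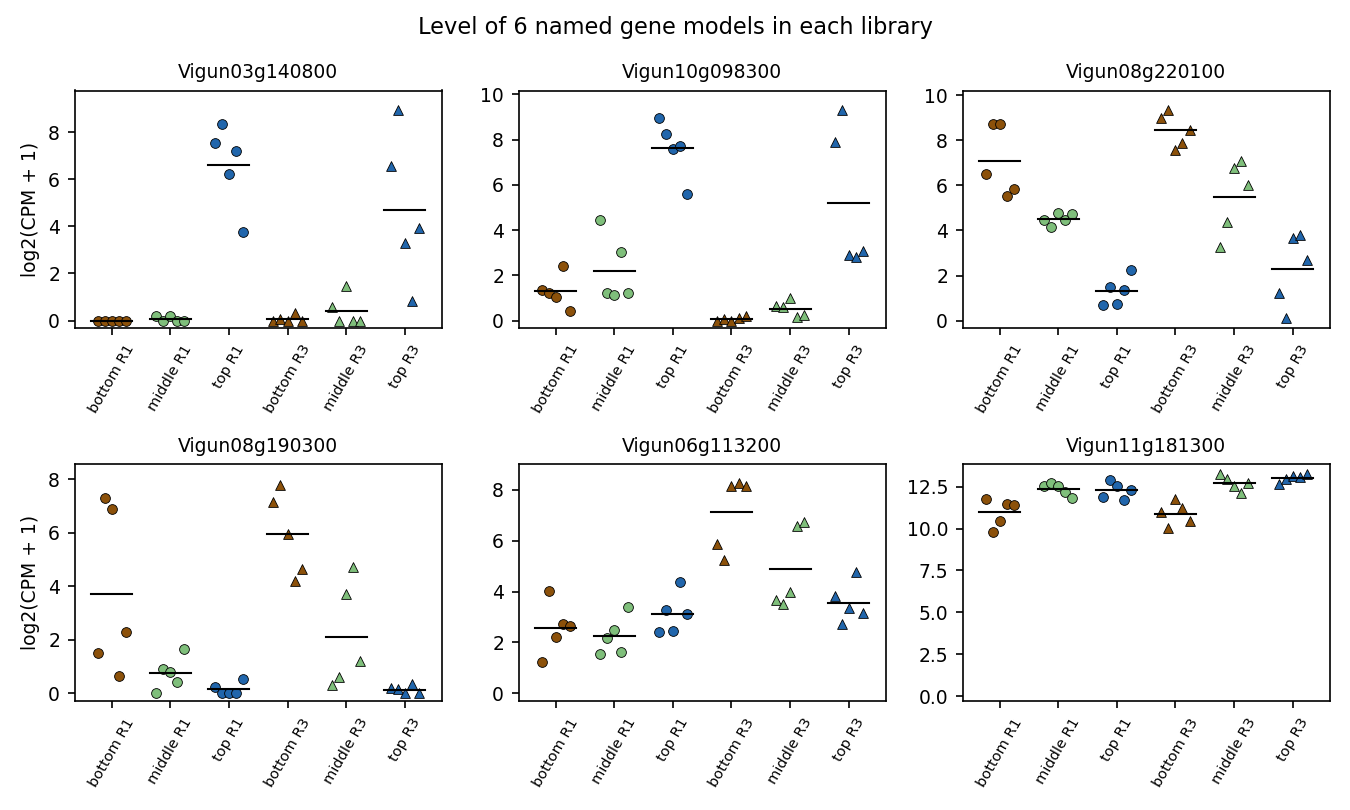
Level of 6 named gene models as log2(CPM + 1) in each of the 30 libraries, grouped by position and stage, with a line at the mean of each group. Vigun03g140800 and Vigun10g098300 are high in top leaves with a wide spread at R3, Vigun08g220100 is highest on average in bottom leaves, Vigun08g190300 varies widely in bottom leaves at R1 (0.539 to 156 CPM), Vigun06g113200 is highest in bottom leaves at R3, and Vigun11g181300 is lowest in bottom leaves.

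Genes were classed by position where they passed the test at least 2-fold, in 1 direction, against both other positions and at both stages, which 1053 genes did. The class highest at the top had 479 genes, most of them at low levels. Their median was 2.69 CPM as a mean over all 30 libraries, which includes the positions where they are low. A mean of at least 10 CPM was reached by 103 of them and 100 CPM by 7. The median was 13.9 CPM in the class lowest at the top, 11 CPM highest at the bottom and 11.7 CPM lowest at the bottom. The most abundant of the 479 were Vigun01g115300 and Vigun11g197400 (chromosome 11, 39647845 to 39649896, minus strand, 2 exons). Vigun11g197400 was at 830 ± 717 CPM in top, 7.52 ± 6.54 CPM in middle and 0.837 ± 0.536 CPM in bottom leaves at R1. At R3 it was at 663 ± 1180 CPM in top leaves, from 3.2 to 2740 CPM, which overlaps middle leaves (up to 4.04 CPM). Its top versus middle call at R3 ended in a fit of the 2 groups alone (adjusted p = 0.14), and without top replicate 2 its log2 fold change there was 6.14, not 8.33, and that over bottom leaves 7.82, not 10.02. The class lowest at the top had 43 genes, led in abundance by Vigun03g020100 and by Vigun07g216700 (chromosome 7, 33837827 to 33838935, plus strand, 2 exons), which was at 581 ± 347, 137 ± 99.1 and 34.2 ± 10.8 CPM in bottom, middle and top leaves at R1. The class highest at the bottom had 137 genes, led by Vigun03g089000 (chromosome 3, 7470540 to 7474672, plus strand, 19 exons; 2250 ± 883, 1110 ± 228 and 611 ± 108 CPM at R1) and Vigun08g027100 (chromosome 8, 2428541 to 2432595, plus strand, 11 exons; 1270 ± 638, 572 ± 219 and 422 ± 164 CPM). Lowest at the bottom were 393 genes, led by Vigun11g181300 and by Vigun07g296000 (chromosome 7, 40641707 to 40644356, plus strand, 7 exons), at 831 ± 1120, 7630 ± 1240 and 5710 ± 1490 CPM at R1 with bottom libraries from 30.8 to 2750 CPM. Its log2 fold change for middle versus bottom went from 3.20 to 4.44 without bottom R1 replicate 4, and from 2.68 to 3.35 at R3 without bottom replicate 3. That for top versus bottom went from 2.78 to 4.02 and from 2.71 to 3.39 in the same fits. By edgeR 0 genes were classed highest in the middle, but 1 was with DESeq2, with either replicate block or without TMM scaling, and up to 2 were over the pairs of libraries left out. In the class lowest there was 1 gene, Vigun08g079600 (chromosome 8, 16366558 to 16376102, plus strand, 3 exons), named after its values were seen, at a mean of 0.727 CPM. With 1 library left out, calls against the middle ended for several of these genes. For Vigun07g296000 this held in 8 of 10 fits at R1 and 6 of 10 at R3 (highest adjusted p = 0.089 in both). A fit of the 2 groups alone also ended its calls for top versus bottom at R3 (adjusted p = 0.06) and for middle versus bottom at R1 (0.093) and R3 (0.077). It ended those of Vigun03g089000 (0.07) and Vigun08g027100 (0.087) for middle versus bottom at R1. With 1 library left out, those ended at R1 in 5 of 10 fits for Vigun03g089000 (highest 0.1) and 6 of 10 for Vigun08g027100 (0.15). For top versus middle it held in 5 of 10 for Vigun07g216700 at R3 (0.096), and for Vigun08g079600 in 3 of 10 at R1 (0.082) and at R3 (0.12). The size of each class rests on few libraries: over the 60 pairs of libraries left out, 1 to 874 genes were highest and 0 to 111 lowest at the top, and 1 to 216 were highest and 9 to 715 lowest at the bottom. The total was 354, 60 and 82 without replicate numbers 1, 2 and 3.

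At the other end, 237 of the 1761 genes with a mean of at least 100 CPM were even over the canopy and both stages, with all 15 differences between group means under 0.5 (log2) and a coefficient of variation under 25% over the 30 libraries. Their median coefficient of variation was 15.4%. The most abundant were Vigun04g096500 (chromosome 4, 20546579 to 20549779, plus strand, 3 exons), at group means from 2330 to 2640 CPM and a coefficient of variation of 17.3%, and Vigun09g108850 (chromosome 9, 22998866 to 23004610, minus strand, 14 exons), at 2020 to 2750 CPM and 17.2%. Scaled by library size alone, 185 genes met the rule, 115 of them among the 237.

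The second question was what changed between R1 and R3 at one position. All R1 libraries came from week 5.5 and all R3 libraries from week 6.5, so stage cannot be told apart from the time since planting. In bottom leaves 3295 genes differed, 1564 higher and 1731 lower at R3. Vigun08g105100 (chromosome 8, 26150815 to 26154154, plus strand, 4 exons) rose from 2.91 ± 4.61 to 103 ± 51.8 CPM (log2 fold change 5.12, SE 1.05, edgeR adjusted p = 0.0026), and Vigun06g113200 (chromosome 6, 24165268 to 24166267, plus strand, 2 exons) from 6.24 ± 5.41 to 192 ± 132 CPM (4.93, SE 0.82, adjusted p = 0.00066). Vigun05g237800 (chromosome 5, 43087711 to 43093343, plus strand, 10 exons) fell from 30.6 ± 42 to 0.578 ± 0.528 CPM (-5.65, SE 1.35, adjusted p = 0.007). Vigun10g139700 (chromosome 10, 35599024 to 35607101, minus strand, 9 exons) fell from 441 ± 764 to 16 ± 5.22 CPM (-4.79, SE 1.32, adjusted p = 0.016), with 1 R1 library at 1810 CPM and the others from 53 to 147 CPM; without that library, replicate 4, the call ended (-2.65, adjusted p = 0.12). Without R1 replicate 2 the fold changes (log2) were 6.84 for Vigun08g105100, 5.59 for Vigun06g113200 and -4.44 for Vigun05g237800. The count was 1801 and 1852 without R1 replicates 1 and 4, 1813 and 2163 without R3 replicates 4 and 5, and 1189 in a fit of the 2 groups alone. Over the 20 pairs of libraries left out it ran from 423 to 4029. Without TMM scaling 986 genes were higher and 1675 lower.

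In middle leaves 504 genes differed between the stages, 216 higher and 288 lower at R3. Vigun01g220300 (chromosome 1, 39403274 to 39405050, plus strand, 5 exons) rose from 0.595 ± 0.348 to 8.61 ± 3.38 CPM (log2 fold change 3.85, SE 0.65, edgeR adjusted p = 0.0063) and Vigun08g172300 (chromosome 8, 34322277 to 34323927, minus strand, 4 exons) from 0.478 ± 0.484 to 6.70 ± 7.16 CPM (3.81, SE 0.91, adjusted p = 0.027). Vigun08g142100 (chromosome 8, 31459178 to 31461712, minus strand, 3 exons) fell from 13.5 ± 7.57 to 4.15 ± 0.878 CPM (-1.71, SE 0.43, adjusted p = 0.034) and Vigun09g161100 (chromosome 9, 32849884 to 32851506, minus strand, 1 exon) from 8.22 ± 1.26 to 2.70 ± 1.44 CPM (-1.60, SE 0.30, adjusted p = 0.0098). The log2 fold change of Vigun08g172300 was 4.59 without R1 replicate 5 and 2.89 without R3 replicate 4. Its call ended without R1 replicates 1, 3 and 4 (adjusted p = 0.076, 0.065 and 0.086) or R3 replicates 3 and 4 (0.052 and 0.1) and in a fit of the 2 groups alone (0.053). That of Vigun08g142100 ended without R1 replicates 1, 3 and 4 (0.098, 0.057 and 0.12) or R3 replicates 2, 3, 4 and 5 (0.065, 0.091, 0.096 and 0.071) and in a fit of the 2 groups alone (0.052). Of the 216 and 288 genes, 153 and 199 changed the same way in bottom leaves, where independent lists would share 17 and 25, and none was called in opposite directions. The 2 lists are not independent, because same-numbered bottom and middle libraries share deviations (mean correlation 0.32 at R1 and 0.23 at R3). How much of the overlap this gives was not tested. The count was 118, 136 and 67 without R1 replicates 1, 3 and 4 and 1402, 233, 73, 185 and 184 without R3 replicates 1 to 5 in that order. It was 1433 with DESeq2, 259 without the filter on low counts, 234 in a fit of the 2 groups alone, 1 to 1507 over the 20 pairs of libraries left out, and 79 higher and 211 lower without TMM scaling.

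In top leaves 316 genes differed between the stages, 162 higher and 154 lower at R3. Vigun03g399500 (chromosome 3, 60594989 to 60597833, plus strand, 5 exons) rose from 1.60 ± 0.214 to 26.7 ± 27.9 CPM (log2 fold change 4.05, SE 0.78, edgeR adjusted p = 0.0082; 3.32 without R3 replicate 2) and Vigun05g017900 (chromosome 5, 1451679 to 1452812, plus strand, 1 exon) from 2.99 ± 0.46 to 42.9 ± 30.5 CPM (3.84, SE 0.70, adjusted p = 0.0065). Vigun02g047800 (chromosome 2, 18734564 to 18736710, minus strand, 2 exons) fell from 16 ± 8.24 to 3.33 ± 1.16 CPM (-2.25, SE 0.42, adjusted p = 0.0067) and Vigun06g072000 (chromosome 6, 20281299 to 20289650, minus strand, 16 exons) from 221 ± 44.4 to 56.1 ± 26.2 CPM (-1.98, SE 0.48, adjusted p = 0.033). The call of Vigun06g072000 ended without R1 replicates 1, 2, 3 and 4 (adjusted p = 0.052, 0.075, 0.072 and 0.076) or R3 replicates 1, 3, 4 and 5 (0.071, 0.088, 0.076 and 0.097). Those of Vigun03g399500 and Vigun02g047800 ended in a fit of the 2 groups alone (0.076 and 0.058). Scored in top libraries, the 216 genes higher at R3 in middle leaves rose from -0.39 ± 0.04 to 0.19 ± 0.21 and the 288 lower genes fell from 0.34 ± 0.02 to -0.20 ± 0.13 (SD, n = 5; exact permutation test, two-sided, p = 0.0079 each, adjusted 0.011). Scored in the same way, the 1731 genes lower at R3 in bottom leaves fell from 0.48 ± 0.06 to 0.19 ± 0.13 (exact permutation p = 0.016, adjusted 0.019), and the 1564 higher genes went from -0.34 ± 0.16 to -0.13 ± 0.29 without passing (exact p = 0.18). With labels exchanged only within same-numbered pairs, the 3 passing changes had an exact p = 0.0625 each. This is the smallest p that 5 pairs can give, so that exchange cannot pass and does not decide them. Same-numbered middle and top libraries share deviations too (mean correlation 0.23 at R1 and 0.19 at R3). Neither test removes this for the 216 and 288 genes, which middle libraries chose. The count of 316 became 1523 without R3 replicate 2, and ran from 1 (without R1 replicates 4 and 5) to 3488 (without R3 replicates 1 and 2) over the 20 pairs of libraries left out. It was 170, 178, 146 and 86 without R1 replicates 1, 2, 3 and 4, and 200, 175 and 126 without R3 replicates 3, 4 and 5. Other counts were 858 with DESeq2, 45 in a fit of the 2 groups alone, and 104 higher and 755 lower without TMM scaling, which moved the median of all genes by -0.18.

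**Figure D5:**
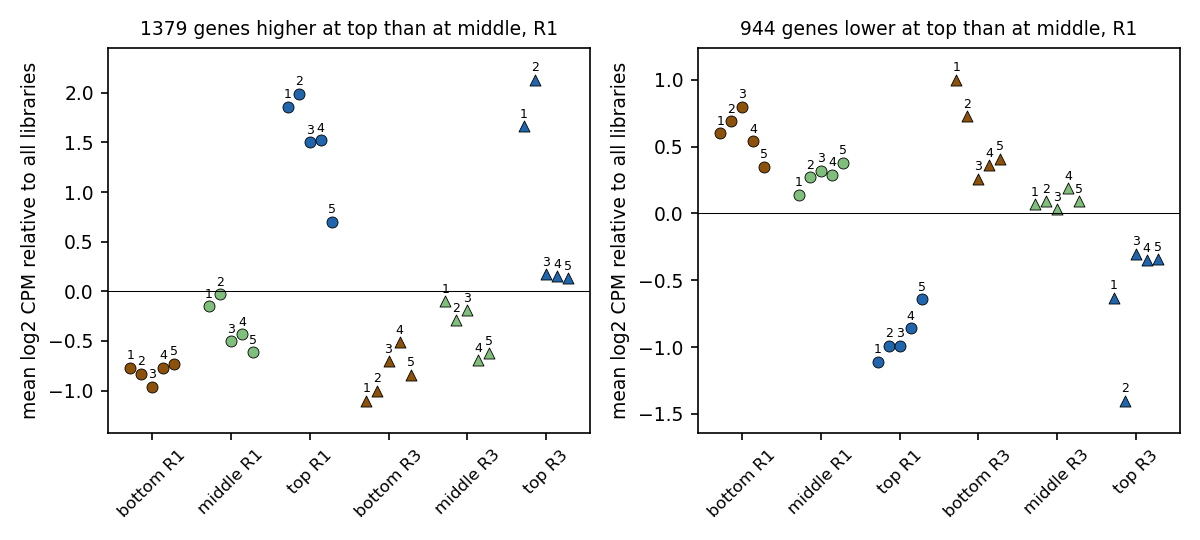
Mean log2 CPM, relative to all libraries, of the 1379 genes higher (left) and the 944 genes lower (right) at the top than in the middle at R1, in each library; numbers are replicates. The top and middle R1 libraries chose these genes, so their distance is in part selection. Top R3 replicates 1 and 2 score 1.66 and 2.13 on the left, and replicates 3, 4 and 5 score 0.17, 0.15 and 0.13.

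Whether the top to bottom difference itself changed between the stages was tested as an interaction. The edgeR quasi-likelihood test called 0 genes (smallest adjusted p = 0.052), and DESeq2 called 464. An unadjusted p under 0.05 was reached by 3089 genes, against 1014 if all genes were independent and unchanged. Other groupings of the same libraries gave a median of 1262 and up to 4265. Of 30 groupings, the real one included, 4 gave at least 3089, so chance can give this count. The count of edgeR calls was 10 and 60 without top R3 replicates 1 and 2, and over the 40 pairs of libraries left out it ran from 0 to 1389 (without both), with a median of 0. It was 298 and 2 without bottom R1 replicates 2 and 3, 14, 1 and 2 without bottom R3 replicates 2, 3 and 4, 1 without top R1 replicate 5, 22 with the size factors of DESeq2 in edgeR, and 2 in a fit of the 4 groups alone or with the replicate number as a block. The stage change of the 216 genes higher at R3 in middle leaves was 0.91 in bottom and 0.57 in top leaves, a difference of 0.34 that did not pass an exact permutation test (p = 0.40, adjusted 0.58).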

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

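The tests on the spread of the top R3 libraries, the groupings that respect replicate numbers, the refit at equal depth, and the fits that leave out pairs of libraries, were chosen only after the results were seen. The other tests in this part were set down before.

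Other groupings of the same libraries tell which counts chance can give; 30 of the possible groupings were drawn for each result, the real one included. The smallest share that 30 groupings can give is 1 of 30, and shares were not adjusted for the number of results. Such a share argues against chance without excluding it. It was found for 5 results, where only the real grouping gave as many genes. These are top versus bottom at R1 (8731, highest other 4790) and R3 (10534, highest other 5203), R3 versus R1 in bottom (3295, highest other 2312) and middle leaves (504, highest other 1), and the position classes (1053, highest other 0). For the classes, positions were exchanged only within a stage and replicate number. That exchange also mixes top with bottom leaves, so it cannot test the steps to and from the middle on which the classes rest. Neighbouring positions of a stage share deviations by number, so they were set against the 16 splits that part all 5 same-numbered pairs, too few for a share under 0.05. For middle versus bottom the real split gave 1581 at R1 (highest other 0) and 4570 at R3 (highest other 1492). For top versus middle it gave 2323 at R1 (highest other 0) and 1288 at R3 (highest other 1). Among 30 splits drawn without regard to pairs, the test set down before, the highest others were 3, 638, 0 and 1365, in the same order. For top versus middle at R3 the 1365 exceeded the real 1288. There 2 of the 30 splits, the real one included, gave as many genes, so by that test chance could not be excluded. Nor could chance be excluded for R3 versus R1 in top leaves, where 3 of 30 gave as many (316, highest other 3974). The same held for the interaction counted at unadjusted p under 0.05, where 4 of 30 did (3089, highest other 4265). The grouping with 3974 genes set top R1 replicates 1, 2 and 3 with top R3 replicates 1 and 2 against the rest, a structure of the samples that stage does not give. Top R1 and top R3 libraries of equal number also went together (correlations from 0.01 to 0.53), which these groupings ignore.

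Top leaves at R3 lie far apart in the genes that separate top from middle leaves at R1. The mean log2 level of the 1379 higher genes, relative to all libraries, was 1.66, 2.13, 0.17, 0.15 and 0.13 in top R3 replicates 1 to 5, against -0.69 to -0.10 in middle R3 libraries and 0.70 to 1.99 in top R1 libraries, which chose these genes and so lie high in part by selection. A swap of labels with a middle R3 library is argued against by a gap of 0.22 between the lowest top and the highest middle library, and a swap with a top R1 library by a gap of 0.34 in genes that fell with stage in middle leaves. Scaling is argued against because in the library farthest from its group's median, replicate 2, the higher genes moved by 1.96 and the lower genes by -1.05. A swap with a sample outside the series stays open, and no biological explanation was tested, since the labels give no further group.

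More genes differed between R3 and R1 in bottom leaves (3295) than in top leaves (316), and the difference itself passed for 0 genes with edgeR (3089 at unadjusted p under 0.05; 464 with DESeq2). Both counts depend on few libraries (bottom: 1801 without R1 replicate 1 and 423 without R1 replicates 1 and 4; top: 1523 without R3 replicate 2 and 3488, above 3295, without R3 replicates 1 and 2), and at equal depth the bottom count was still 10.8 times the top count, which argues against depth. A shift of bottom leaves along the top minus middle difference at R1 is argued against by a correlation across genes of 0.02, from -0.05 to 0.13 with 1 library left out. This does not cover the first principal component. On it the mean score went from -45 at R1 to -86.3 at R3 in bottom leaves. It went from 12.3 to -12.5 in middle and from 75.7 to 55.7 in top leaves. A shift along that component was not tested and stays open. A larger spread between top libraries cannot be told apart from a smaller change: the ratio of bottom to top in the spread of log2 fold changes beyond their standard errors was 1.85 and at lowest 1.45 with 1 library left out, above the bound of 1.3 set beforehand, but that bound did not allow for 2 libraries of a group standing apart: of the 40 pairs left out, 1 gave 1.09 (top R3 replicates 1 and 2, the pair first noticed by its values) and the others 1.46 to 2.46. A true difference between canopy positions stays open and untested beyond the interaction.

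In 7 of 100 groups of 5 values, 1 library lay far from the others by Dixon's test at 95%. For independent, normally distributed values chance alone gives about 1 in 20, or 5. Many of the values are CPM of genes chosen for their fold changes or scores of related gene groups. The 5 is therefore a rough guide, and 7 against 5 says little either way. Total counts were 17.4 M in bottom R1 replicate 5, with the others from 11.5 to 13.1 M. The score of genes lower at the top than at the bottom at R1 was -0.9896 in top R3 replicate 2, with the others from -0.452 to -0.257. The score of genes lower at R3 than at R1 in middle leaves was 0.3814 in top R1 replicate 4, with the others from 0.33 to 0.342. Vigun08g105100 was at 11.03 CPM in bottom R1 replicate 2 (others 0 to 2.04), and Vigun10g139700 at 1807 CPM in bottom R1 replicate 4 (others 53 to 147). Vigun08g172300 was at 19.31 CPM in middle R3 replicate 4 (others 2.5 to 5.64), and Vigun03g399500 at 1.223 CPM in top R1 replicate 2 (others 1.66 to 1.72).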

How the results depend on the processing

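Chosen only after the data were seen were library size alone for the counts of changed genes, equal depth, the replicate block within stage, and the pairs of libraries left out; the other alternatives were set down before. A 2-fold minimum gave 4601 and 5980 genes for top versus bottom at R1 and R3, 828 and 2309 for middle versus bottom, 1508 for top versus middle at R1, and 1506, 143 and 131 for R3 versus R1 in bottom, middle and top leaves. DESeq2 gave 2552 for middle versus bottom at R1, 2391 for top versus middle at R3, 1433 and 858 for R3 versus R1 in middle and top leaves, and 464 for the interaction. A fit of only the groups compared gave 808 for middle versus bottom at R1, 3710 and 33 for top versus middle at R1 and R3, 1189, 234 and 45 for R3 versus R1 in bottom, middle and top leaves, and 2 for the interaction. Library size alone gave 2650 for middle versus bottom at R1 and 290 and 859 for R3 versus R1 in middle and top leaves. For the interaction, the size factors of DESeq2 in edgeR gave 22, the replicate block 2, equal depth 10 and the block within stage 51. No filter gave 259 for R3 versus R1 in middle leaves, no fold threshold 1837 position classes, and a minimum of 50 CPM 776 even genes. With 1 library left out, the lowest and highest counts were 7508 and 8888 for top versus bottom at R1, 9749 and 10579 at R3, 460 and 2485 for middle versus bottom at R1, 3184 and 5309 at R3. They were 1149 and 3070 for top versus middle at R1, 83 and 2000 at R3, and 1801 and 4002 for R3 versus R1 in bottom, 67 and 1402 in middle and 86 and 1523 in top leaves, and 0 and 298 for the interaction. With 1 replicate number left out of all groups they were 60 and 847 for the position classes and 199 and 286 for the even genes. With 2 libraries of a group left out, over all pairs, the lowest was 5524 for top versus bottom at R1, 1715 for middle versus bottom at R3, 45 for top versus middle at R1, 423 for R3 versus R1 in bottom leaves and 217 for the classes, and the highest was 1389 for the interaction. The lowest and highest were 15 and 3148 for middle versus bottom at R1, 1 and 2917 for top versus middle at R3, and 1 and 1507 in middle and 1 and 3488 in top leaves for R3 versus R1. A fit without 1 pair of top R3 libraries, chosen for their values, had been run first and gave way to all pairs; that pair gives the 3488 and the 1389. Of 1791 alternative values of log2 fold changes for named genes, 1622 kept their direction and side of the threshold, 120 no longer passed, 14 newly passed and 35 changed sign, none of them where either value passed (lowest adjusted p = 0.76). For Vigun07g296000, top versus middle at R3 went from 0.04 to -0.26 (replicate block), -0.44 (block within stage), -0.09 (library size), and -0.13 to 0.27 with 1 library left out. For Vigun01g219300 it was 0.00, then 0.03 (size factors of DESeq2 in edgeR, and DESeq2), 0.02 (block; 2 groups alone), 0.04 (block within stage), and -0.14 to 0.11 with 1 library left out. With 1 library left out, Vigun08g079600 ran from -0.90 to 0.22 for top versus bottom at R3 (-0.04; 0.00 with the size factors), and Vigun11g181300 from -0.24 to 0.07 for top versus middle at R1 (-0.06). Of 2 more genes, each most abundant in 1 library, Vigun05g142900 ran from -0.33 to 0.04 for top versus middle at R1 (-0.17) and from -0.12 to 0.22 for R3 versus R1 in top leaves (0.05; -0.05 with the block, -0.12 by library size). Vigun08g036100 ran from -0.10 to 0.50 in bottom (0.25) and -0.29 to 0.91 in top leaves (0.26) for R3 versus R1. The replicate block changed no count of changed genes by more than 1.5 times apart from the interaction (1571 genes for middle versus bottom at R1, the only pair of groups in which every same-numbered correlation passed 0.1). Between neighbouring positions of a stage, same-numbered libraries shared deviations beyond other pairs by 0.31 (highest permuted 0.23, permutation p = 1e-04, the smallest that 9999 permutations can give). Between top and bottom leaves this excess was 0 at R1 and -0.01 at R3. The replicate block fits 1 effect per number for all 6 groups, so it cannot take up such sharing in full. Counts that the block left alike therefore do not show that the sharing is without effect. The tests of gene lists in 5 comparisons, with their alternatives, were not run, because 0 identifiers matched a named gene.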

Other observations

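The comparisons of gene structure, contigs and runs of neighbouring genes were chosen only after the data were seen; the tests of the 2 explanations for neighbouring genes were set down before their results, and limited to chromosomes after.

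The 1564 genes higher at R3 than at R1 in bottom leaves had a median of 5 exons and 16.6% had a single exon, the 1731 lower genes had a median of 8 and 9.47%, and all 20284 tested genes a median of 7 and 12.7%; no test was run on these values. For top versus bottom the medians were 7 exons in higher and 6 in lower genes at R1 and 7 in both at R3.

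Genes on contigs not placed on the 11 chromosomes went 1 way. Of 221 tested, 76 (34.4%) were higher at the top in both stages, against 17.5% on chromosomes (Fisher's exact test over genes, which are not independent, p = 2.4e-09), and 0 were lower in both, against 15.6% (p = 1.2e-16; 0 of 221 allows up to 1.36%). Of the 76, 57 had 1 exon and 20 lay on a single contig, and 9 shared the length of 123 bases, so these counts are uncertain where near-identical copies share reads.

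Tested genes next to each other on a chromosome differed together between top and bottom leaves. Gene models that were not tested were passed over, so adjacent here means nearest among the tested genes. Among genes at least 2-fold higher or lower in both stages, 452 adjacent pairs on chromosomes went the same way, against a mean of 315 and a highest of 373 in 1000 shuffled orders (permutation p = 0.001, the smallest they can give), and 17 runs of at least 4 genes stood against a shuffled mean of 2.97 (highest 10); with contigs there were 475 pairs and 20 runs. Reads shared by overlapping models, or transcription running on into the next gene, are argued against as the whole cause by a ratio of 1.55 to shuffled order in pairs more than 5 kb apart (287 pairs, highest shuffled 225). Tandem copies changing together cannot be told apart from a shared local cause, since the excess on the same strand over that on opposite strands was 0.38 (log2), between the bounds of 0 and 0.5, and sequences were not analysed here. No biological explanation was tested.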
